A study of Mus musculus with 34 samples.

How the data were processed

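Colonic lamina propria macrophages of C57BL/6 mice were sorted by surface markers, and their polyadenylated RNA was captured with oligo-dT beads, amplified by in vitro transcription and fragmented for sequencing, per the labels' protocols. Protocols of this kind often read the 3' ends of transcripts, but the labels do not say so, and no correction for gene length was made. Per the submitters' processing notes the authors used bcl2fastq, HISAT 0.1.6, HOMER and the mouse build mm9. The roles and order of these tools, the annotation, the use of strand and the treatment of reads that fit several genes are not given in the sources used here. Gene symbols were used as the tables give them. Of 9022, 8816 and 8793 genes in the first, rescue and neutrophil table, 8754, 8559 and 8610 symbols were found among GENCODE M21 names, and 7897 were shared by the 3 tables. No coordinates are given, since the genome used here is a later build than mm9.

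The deposited values are signal values, not raw counts: each column held the reads per gene divided by 1 factor per library. This was read from the values, since every value of a library was a whole multiple of what 1 read is worth, within a tolerance of 0.01 read, for 100% of values. The factors bring the libraries' median genes to about the same value, and who computed them, or the gene filter, is not stated. For ko_igg 16 and wt 3 too few values lay low enough for this check, so their reads are not claimed as recovered. Rows with no gene name, 15399 in the first and 15605 in the rescue table, held no number and were left out. The 3 tables hold different genes and were normalized separately, so each test was made within 1 table, and levels set side by side across tables are not comparable. A table that keeps only genes above some level cannot show a gene that was low in all its libraries, and a division by median genes cannot show a change of all genes at once. Reads per library ranged from 747046 to 2775974 in the first 2 tables, and no fold is given where a group held at most 1 read of a gene per library.

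Groups were taken from the sample titles. For the neutrophil table the treatment label describes bone marrow chimeras and gives all libraries the same injection, against the titles, and the titles were followed. The genotype of the libraries titled littermate is not stated, nor the meaning of 5C5 in the titles. The design planned a count test. As the tables hold normalized values, the test planned for that case was used instead. The values were put on the scale log2(value + pseudocount), with the median over libraries of the smallest value above 0 as pseudocount (1.31 in the first, 0.997 in the rescue and 0.982 in the neutrophil table), which understates changes of low genes. Genes whose mean lay in the lower quartile were removed (means up to 53.2, 40.4 and 68.0), leaving 6766, 6612 and 6594. All groups of a table entered 1 limma fit (limma 3.58.1, R 4.3.3) with a mean-variance trend and robust variances, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Every adjusted p of a gene is from limma, and changes are log2 with their standard error (SE). Means are given with SD over libraries.

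Of 26 gene lists written before the data were examined, 22 kept at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data, adjusted over the lists of a comparison. The other lists were not tested. Of the list calls, those of the dendritic cell list in 3 comparisons and of the glycolysis list in 2 hold with an estimated correlation, and the others were lost. For these calls the estimated correlation was below the preset one (-0.019 and -0.024). The 3 comparisons share the IL10R libraries and the 2 share the wt libraries, so they are not independent. Only 3 dendritic cell markers were tested there. The first table's called genes, tested as sets in the other tables, kept 1 call, that of the lower genes in ko_igg against wt. Genes named in the text were chosen by a rule fixed before the data were examined: Il10ra and Il23a, then Il1b, Il6, Tnf and Il12b, in each comparison the 5 highest and 5 lowest called genes above the median level whose libraries do not overlap, and up to 4 called members per list with the smallest adjusted p. Predicted genes, antigen receptor segments and sex-linked genes were left out, and some genes the rule names are not reported here. Genes named for other reasons are said to be so, and the overlap and neighbour genes were named from the calls. The tables list near-identical genes that can share reads, such as H2-Q7 with H2-Q9 and H2-T22 with H2-T9, which are uncertain.

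No 2 libraries of a group agreed within counting noise, the smallest chi-square per degree of freedom between recovered reads being 3.59, so all 34 were kept as separate. The fits were first tested on simulated data with 200 changed genes per comparison. For genes changed 2-fold and 4-fold the share recovered was 42% and 91% in IL10R against CXhet (6766 genes), 55% and 91% in IL10R against CX, 84% and 99% in IL10R_P19 against IL10R, 53% and 95% in IL10R_P19 against CX, 68% and 96% in IL10R_abx against littermate_abx, 72% and 97% in IL10R_abx against IL10R, and 62% and 93% in littermate_abx against CX (6612 genes each). In the neutrophil table (6594 genes) it was 57% and 95% for ko_igg against wt, 54% and 88% for ko_ly6g against ko_igg and 45% and 87% for ko_ly6g against wt. False calls numbered 3 to 15, and no changed gene was called in the wrong direction. The simulated genes varied independently, each with the same spread in all groups. Genes that move together and libraries that stand apart were therefore not covered, so these shares and false calls may not hold for the real data.

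The alternatives were another scaling (median ratio, quantile), other pseudocounts, no filter or a stricter one, limma without a trend, a minimum change of 1 on the log2 scale, a fit of the compared groups alone, a replicate block in the first table and leaving out each library in turn. Chosen after the data were seen were a quasi-likelihood test on the recovered reads with edgeR 4.0.16 (first and rescue table only), the epithelial marker score of each library as a covariate, and leaving out 2 pairs of libraries. The epithelial score and the epithelial share of reads include Reg3b and Reg3g, which were themselves among the most changed genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.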

Results

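RNA of macrophages sorted from the mouse colonic lamina propria was measured in 34 libraries of 10 groups, deposited in 3 tables. The sort, per the labels, kept CD45+ CD11b+ CD11c-intermediate CD64+ cells that lacked Ly6c and CD103, from C57BL/6 mice. The first table holds 3 libraries titled CXhet and 3 titled IL10R. The rescue table holds 2 libraries titled CX, 5 titled IL10R, 4 titled IL10R_P19, 4 titled IL10R_abx and 3 titled littermate_abx. The neutrophil table holds 4 libraries titled wt, 3 titled ko_igg and 3 titled ko_ly6g. IL10R stands for mice with macrophages deficient in the IL-10 receptor alpha chain, as the series title says. P19 was read as the p19 subunit of IL-23, encoded by Il23a, and abx as antibiotics. The reads of the listed genes came to 1458726 to 2487074 per library in the first table and 747046 to 2775974 in the rescue table. In the neutrophil table they came to 1028567 to 4525047 in the 8 libraries whose reads could be recovered. The labels do not say that the libraries of a group came from separate animals, so each p-value measures the spread between these libraries, which may be technical.

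Il10ra, the targeted gene, was lower in the deficient libraries of each table, with 1 exception. In the first table it stood at 689, 501 and 371 in the CXhet libraries and at 9.30, 361 and 65.9 in the libraries labelled IL10R 1, 2 and 3. The change of -2.99 on the log2 scale (SE 1.09, n = 3 and 3) did not pass (limma adjusted p = 0.138), and the library labelled IL10R 2 lay beside the lowest CXhet library. Its other genes did not place it with CXhet. On the first principal component of the tested genes (67.3% of the variance) it lay at 52.9. IL10R 1 and 3 lay at 16.6 and 24.7, and the CXhet libraries at -38.0 to -25.6. Every direction given for the first table includes the library labelled IL10R 2. In the rescue table Il10ra was 266 ± 25.5 in CX (SD, n = 2) and 158 ± 28.9 in littermate_abx (n = 3), against 14.7 ± 10.0 in IL10R (n = 5), 8.67 ± 4.20 in IL10R_P19 (n = 4) and 5.20 ± 3.43 in IL10R_abx (n = 4). In the neutrophil table it was 417 ± 276 in wt (n = 4), 92.3 ± 17.2 in ko_igg (n = 3) and 46.2 ± 17.0 in ko_ly6g (n = 3). The labels state neither which part of the gene was deleted nor which part of a transcript was read, so a value left in a deficient library does not by itself go against its label. Il23a was listed in the first table only, at 1.39 to 10.3 in CXhet and 45.9 to 58.2 in IL10R, so it could not be checked in the IL10R_P19 libraries. In the fit without a filter its change was 3.42 (SE 0.58, limma adjusted p = 0.0076). Il12b, which encodes the p40 subunit that IL-23 shares with IL-12, was higher by 3.51 in the same fit (SE 0.61, adjusted p = 0.00852).

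**Figure D1:**
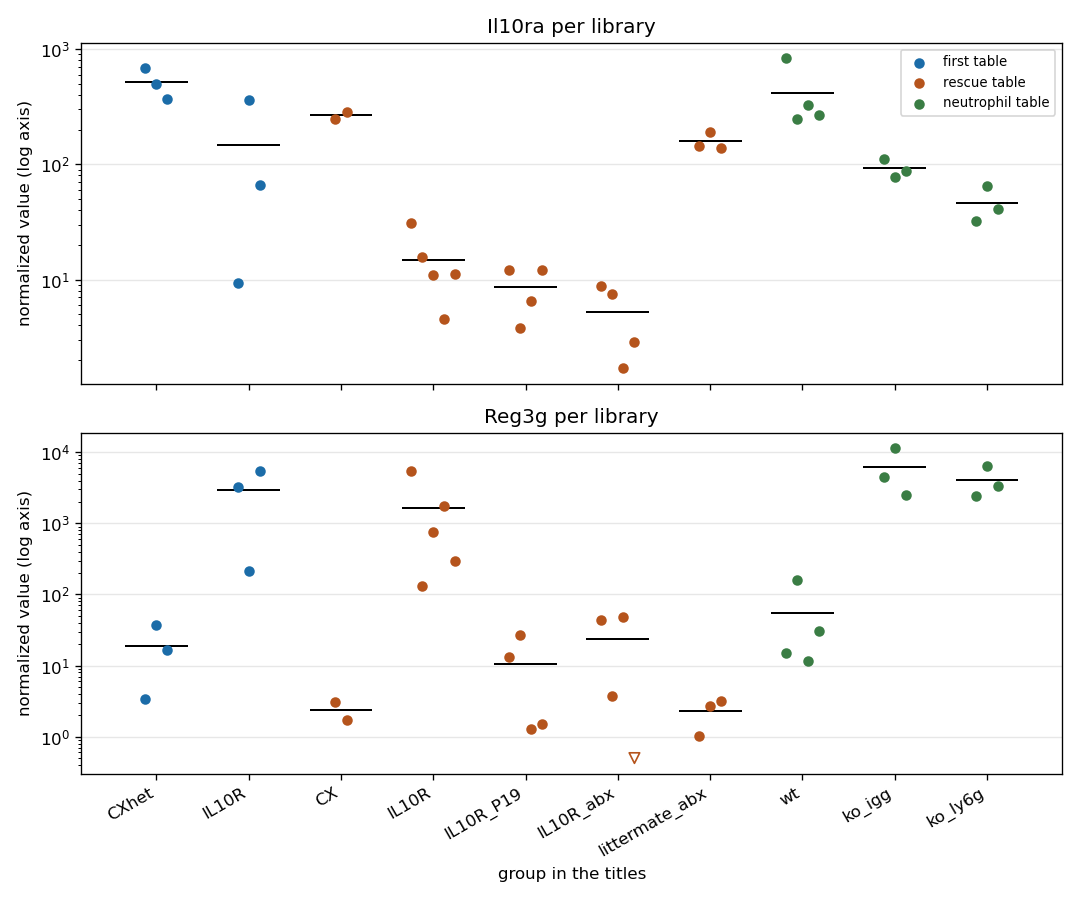
Normalized value of Il10ra (upper panel) and Reg3g (lower panel) in each library of the 10 groups on a log axis, with 1 point per library, colours for the 3 tables and a black line at each group's mean. The open triangle is a library listed at 0. Il10ra lies at 361 in the library labelled IL10R 2 of the first table, and Reg3g lies between 132.7 and 5368 in the IL10R libraries of the rescue table against 1.71 and 3.11 in CX.

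The first comparison asked what differed between macrophages of IL10R and CXhet mice in the first table. The called genes with the largest rises included genes of antibacterial defence, and those with the largest falls included markers of resident macrophages. Nos2, the inducible nitric oxide synthase, was 827 ± 524 in IL10R and 5.79 ± 2.40 in CXhet (SD, n = 3 each), a log2 change of 6.69 (SE 0.47, limma adjusted p = 3.540e-04). Saa3, an acute-phase protein, was 3974 ± 2744 against 42.6 ± 27.5, and the T cell attracting chemokine Ccl5 was 13371 ± 8197 against 172.8 ± 99.2. Hp, the haemoglobin-binding protein haptoglobin, rose by 6.46 (SE 0.96) and Reg3g, an antibacterial lectin, by 6.71 (SE 1.24). Among the largest falls were those of Fcrls at -5.07 (SE 0.49), the folate receptor Folr2 at -4.69 (SE 0.50), the coagulation factor chain F13a1 at -4.44 (SE 0.35), the hyaluronan receptor Lyve1 at -4.39 (SE 0.66) and the pancreatic zymogen protein Sycn at -4.26 (SE 0.40).

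Most tested genes of the interferon and MHC class I lists were called higher in this comparison. Of 16 tested interferon-gamma-inducible GTPases and regulators, 14 were called higher (15 adjusted over the list alone) with a median change of 2.32, among them Gbp4 by 3.12, Gbp2 by 3.47, Igtp by 2.45 and the chemokine Cxcl9 by 4.55. Of 21 type I interferon-stimulated genes, 12 were higher (16 adjusted over the list alone), including Zbp1 by 2.47, Rsad2 by 2.12 and Oasl2 by 1.59. Of 16 genes for MHC class I and the immunoproteasome, 13 were higher (15 adjusted over the list alone), including the peptide transporter Tap1 by 2.51, Nlrc5 by 2.10 and Psmb9 by 2.08. H2-Q7 rose by 2.90, but its reads cannot be told from those of its near copy H2-Q9. Camera, which compares a list with all other tested genes, gave adjusted p = 7.54e-17, 2.72e-11 and 8.04e-13 for these 3 lists, and adjusted p = 0.267 with an estimated correlation for each.

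Parts of the antimicrobial, monocyte and glycolysis lists were higher as well. Of 21 antimicrobial and oxidative defence genes, 12 were higher and none lower (17 adjusted over the list alone), including Irg1, the enzyme that makes itaconate, by 5.26 (SE 0.49) and the receptor Clec4e by 4.91 (SE 0.38). Of 19 monocyte markers, 10 were higher, such as Ly6c1 by 3.04 (SE 0.35), and F13a1 was lower (12 higher and 1 lower adjusted over the list alone). Of 18 glycolysis and hypoxia genes, 9 were higher (15 adjusted over the list alone), including the lactate exporter Slc16a3 by 2.92, Hk3 by 1.75, Pfkp by 1.45 and Hif1a by 1.15. The camera adjusted p of these 3 lists was 4.44e-13, 6.37e-06 and 8.36e-10, and adjusted p = 0.267 with an estimated correlation for each. Smaller parts of 4 other lists were higher. These were 2 of 7 pro-inflammatory cytokines (Il1a by 2.83 and Tnfsf9 by 1.02, 4 adjusted over the list alone), 2 of 6 neutrophil markers (S100a9 by 5.42 and Csf3r by 1.29, 4 adjusted over the list alone), 8 of 30 pattern recognition and NF-kB genes (such as Traf1 by 2.44 and Nod2 by 1.91, 11 higher and 1 lower adjusted over the list alone) and 4 of 13 MHC class II and co-stimulation genes (Cd274 by 1.75, H2-Oa by 1.76, Cd40 by 1.28 and Ciita by 0.95, 6 adjusted over the list alone). With an estimated correlation the adjusted p was 0.267 for the cytokine and neutrophil lists, 0.46 for the NF-kB list and 0.424 for the class II list. Il1b was higher by 1.08 (SE 0.32, adjusted p = 0.0701) and Tnf by 1.12 (SE 0.30, adjusted p = 0.0501), which did not pass. In the fit without a filter Tnf passed (limma adjusted p = 0.0446) and Il1b did not (0.0676), so the call of Tnf depends on the filter. Il6 was not among the genes listed in any table.

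Of 26 tested markers of resident colonic macrophages, 11 were lower, 1 was higher and 14 did not pass (14 lower and 1 higher adjusted over the list alone), with a median change of -1.02. Beside Folr2 and Lyve1, the mannose receptor Mrc1 fell by 2.77 (SE 0.42), the growth arrest protein Gas6 fell by 2.54 (SE 0.38) and the haemoglobin scavenger receptor Cd163 fell by 3.51 (SE 0.61), and the member that rose was the Fc receptor Fcgr1 by 1.05 (SE 0.26). The camera adjusted p was 6.56e-06, and adjusted p = 0.46 with an estimated correlation. Of 24 immediate-early and dissociation stress genes, 4 were lower, namely Egr1 by -1.49, Klf4 by -1.25, Atf3 by -0.96 and Jund by -0.93 (8 adjusted over the list alone, adjusted p = 0.499 with an estimated correlation). Among the lists that camera did not call, matrix remodelling had 4 higher members, such as Inhba by 4.85, and 3 lower, such as Igf1 by -2.35, of 20 (7 and 5 adjusted over the list alone). Chemokines had 3 higher, such as Cxcl10 by 1.74, and 2 lower, such as Pf4 by -2.91, of 16 (4 and 4 adjusted over the list alone). The IL-10 and STAT3 response list had Il1rn higher by 1.54 and Cd163 lower of 19 (3 and 3 adjusted over the list alone). Lysosome and phagocytosis genes had Ctss higher by 1.02 and Cd36 lower by -3.03 of 24 (1 and 1 adjusted over the list alone). No member of the lists for oxidative phosphorylation (27 tested), cell cycle (19) and B and plasma cells (5) was called by limma, and none was adjusted over the list alone. Of the markers of other cells, 1 of 18 epithelial markers was higher (Reg3g) and 1 lower (Phgr1 by -1.55), 1 of 4 dendritic cell markers was higher (Ccr7 by 5.10) and 2 lower (Amica1 by -1.45 and Clec10a by -1.78), and 1 of 9 stromal and endothelial markers was higher (Pecam1 by 0.91), with the same counts adjusted over the list alone.

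In all, 588 of 6766 tested genes were called in this comparison (limma-trend, Benjamini-Hochberg adjusted p under 0.05), 309 higher and 279 lower, of which 481 changed at least 2-fold. The 2 groups' libraries did not overlap in 2192 genes, where chance gives 10% of genes for 3 against 3 libraries. Without CXhet 2 the count was 200, without CXhet 3 it was 273 and without IL10R 3 it was 295, and without the library labelled IL10R 2 it was 470.

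The rescue table held a second comparison of deficient with control macrophages, IL10R (n = 5) against CX (n = 2). Reg3b was 2576 ± 2891 in IL10R and 1.04 and 0.57 in the CX libraries (limma adjusted p = 0.00379), Nos2 was 181 ± 166 against 0.57 and a library listed at 0 (adjusted p = 0.00239), and Clca4b was 378 ± 328 against 0.57 and a library listed at 0 (adjusted p = 0.00199). No fold is given for these 3 because CX held at most 1 read per library. The antimicrobial list as a whole was not called, with 4 of 16 higher and 3 lower (5 higher and 4 lower adjusted over the list alone), a median change of -0.05, a mean of 1.61 and camera adjusted p = 0.52. Lrg1 rose by 5.41 (SE 1.01) and Plet1 by 4.34 (SE 0.96). Fcrls fell by 3.58 (SE 0.74), the sialic acid lyase Npl by 2.74 (SE 0.49), the leukotriene enzyme Ltc4s by 2.64 (SE 0.72), Folr2 by 2.51 (SE 0.75) and the heat-shock cognate Hspa8 by 2.38 (SE 0.56).

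Of 26 resident macrophage markers 17 were lower and none higher (20 adjusted over the list alone, median -1.17), including Mrc1 by -2.33, the growth factor receptor Csf1r by -1.40 and the complement gene C1qc by -1.16. Lysosome and phagocytosis genes were lower in 11 of 24 (18 adjusted over the list alone), such as Ctsl by -1.14 and Cd68 by -0.88, and the adjusted p of both lists was 0.0545 with an estimated correlation. Of 24 stress genes 10 were lower (13 adjusted over the list alone), such as Nr4a1 by -1.34, of 10 MHC class II genes 6 were lower (6 adjusted over the list alone), such as H2-Ab1 by -1.46, of 16 matrix genes 5 were lower (7 adjusted over the list alone), such as Tgfb1 by -1.39, and of 19 IL-10 and STAT3 response genes 3 were lower (4 adjusted over the list alone), including Il10 by -1.52. Oxidative phosphorylation genes were higher in 5 of 26 (5 adjusted over the list alone), such as Cyc1 by 0.82, and with an estimated correlation the adjusted p was 0.254 for these 5 lists. Interferon-gamma-inducible genes were higher in 4 of 14 (9 adjusted over the list alone), such as Iigp1 by 2.76, MHC class I genes in 4 of 16 (11 higher and 2 lower adjusted over the list alone), such as Tap1 by 1.49, and epithelial markers in 3 of 20 (3 adjusted over the list alone), namely Reg3b, Reg3g and Krt20 by 1.29. For these 3 lists the adjusted p was 0.271 with an estimated correlation. Chemokines had 4 of 18 lower, such as Ccl2 by -1.63, and Cxcl9 higher by 2.44, and glycolysis had 2 of 15 higher, such as Pfkp by 1.34, both with adjusted p = 0.265 with an estimated correlation. The dendritic cell markers Amica1 (-1.69), Batf3 (-0.90) and Clec10a (-1.31) were all lower, 3 of 3, and kept their camera call with an estimated correlation (adjusted p = 0.0205). B and plasma cell markers were lower in 2 of 4, the B cell genes Cd22 by -1.18 and Cd79b by -1.55 (2 adjusted over the list alone). Of 14 monocyte markers Cd177 was higher by 2.31 and Ly6c1 by 1.88, and 2 were lower, such as F13a1 by -2.17 (2 higher and 3 lower adjusted over the list alone). Of 5 neutrophil markers 1 was higher (1 adjusted over the list alone), and of 8 stromal and endothelial markers none was called. Camera called none of these 4 lists (adjusted p = 0.0869 to 0.901). Tnf differed by -0.64 (SE 0.48) and Il1b by -0.64 (SE 0.37), which did not pass. Il12b was higher by 2.88 in the fit without a filter (SE 0.85, adjusted p = 0.0428). Of 6612 tested genes 655 were called, 256 higher and 399 lower, of which 277 changed at least 2-fold. The epithelial markers took 1.91 to 2.53% of the reads in IL10R against 1.49 and 1.66% in CX, so their share moved with each of these lists. With the epithelial score as a covariate, which raised the variance 3.51 times, limma called no gene. This score and the share above include Reg3b and Reg3g. The list had a mean change of 1.09, but its 18 other members had a median of 0.32. The lack of calls therefore cannot separate the share of epithelial RNA from the change of Reg3b and Reg3g. With 2 CX libraries, the count was 20 without CX 1 and 94 without CX 3, where the lone CX library is assumed to vary like the other groups, and 413 without IL10R_32.

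Calls of the 3 tables overlapped. Of 5976 genes tested in both the first and the neutrophil table, 94 were called higher and 86 lower in deficient libraries of both, against 13.6 and 8.17 for independent lists (n1 × n2 / N). The first and the rescue table shared 42 higher and 81 lower (9.01 and 17.0 for independent lists), and 72 and 55 were shared by the rescue and the neutrophil table (12.1 and 12.6). Called in all 3 tables were 32 genes higher and 27 lower, and 0 with opposite signs in limma. The higher ones included Nos2, Reg3g, Clca4b, Lrg1, Plet1, Gbp2, Iigp1, Tap1 and Ly6c1, and the lower ones Fcrls, Mrc1, Npl, Pf4, Cd93, Cd81 and Dab2. Not all lists repeated. Type I interferon-stimulated genes, higher in 12 of 21 in the first table, were higher in 1 of 19 in IL10R against CX (median -0.11). In ko_igg against wt they were higher in 3 of 16 (median 0.17). MHC class II genes were higher in 4 of 13 in the first table and lower in 6 of 10 in IL10R against CX. In IL10R against CX, NF-kB genes had 1 higher and 1 lower of 26, and cytokines 1 lower of 6. Hspa8 was lower in IL10R of the first table by 3.99 on the log2 scale (SE 0.22) and of the rescue table, and its change of 0.51 in ko_igg (adjusted p = 0.332) did not pass.

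The next question was what changed when IL-23 p19 was missing as well. IL10R_P19 macrophages (n = 4) were compared with IL10R macrophages (n = 5). Reg3b was 24.9 ± 41.9 against 2576 ± 2891 (log2 change -7.39, SE 1.38, limma adjusted p = 0.0124), Reg3g fell by 6.82 (SE 1.18), Clca4b by 5.35 (SE 0.99), Lrg1 by 4.67 (SE 0.81), Nos2 by 4.09 (SE 0.88) and Plet1 by 3.83 (SE 0.77). The growth factor Igf1 rose by 2.14 (SE 0.35), Npl by 1.93 (SE 0.39), Mrc1 by 1.66 (SE 0.28), the TLR-associated protein Ly86 by 1.63 (SE 0.34) and the cyclooxygenase Ptgs1 by 1.49 (SE 0.25). Of 26 resident macrophage markers 11 were higher and none lower (20 adjusted over the list alone, median 0.73), among them Hpgds by 1.23. The resident marker score (mean log2) of IL10R_P19_100 was 7.63, within the 7.09 to 7.87 of the IL10R libraries. The other IL10R_P19 libraries had 8.36 to 8.46. Lysosome and phagocytosis genes were higher in 3 of 24, namely Npc2 by 0.57, Ctsb by 0.59 and Cd68 by 0.56 (15 adjusted over the list alone), and the adjusted p of both lists was 0.0608 with an estimated correlation. All 3 tested dendritic cell markers, Clec10a (1.33), Batf3 (0.62) and Amica1 (0.87), were higher (adjusted p = 0.00933 with an estimated correlation). Tnf differed by -0.35 (SE 0.39) and, in the fit without a filter, Il12b by -2.63 (SE 0.68, adjusted p = 0.0525), which did not pass. Stromal and endothelial markers had no called member and lay above 0 in 1 of 8 (median -0.72, adjusted p = 0.369 with an estimated correlation). Of 14 monocyte markers 1 was lower, Ly6c1 by -1.59 (2 higher and 2 lower adjusted over the list alone), and camera did not call that list (adjusted p = 0.358). Antimicrobial genes were lower in 3 of 16 (2 higher and 6 lower adjusted over the list alone), epithelial markers in 2 of 20 (Reg3b and Reg3g, 2 adjusted over the list alone), MHC class II genes higher in 1 of 10 (H2-DMa by 0.59, 6 adjusted over the list alone), and these 3 had adjusted p = 0.369 with an estimated correlation. The epithelial markers took 1.51 to 1.77% of the reads in IL10R_P19 and 1.91 to 2.53% in IL10R, so their share moved with each of these lists. With the epithelial score as a covariate, which raised the variance 3.34 times, no gene was called by limma. Reg3b and Reg3g are part of this score, whose list had a mean change of -0.84 and a median of -0.16. The lack of calls thus does not separate the share from the change of these genes.

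Of the genes tested, 127 were called higher and 34 lower in this comparison. On the recovered reads edgeR called 287, 189 higher and 98 lower. With the compared groups alone in the fit, limma called 124 higher and 99 lower, so the balance of directions depended on the fit. Of the first table's 309 higher genes 234 were tested here, with a median change of -0.25 (12 lower, 0 higher called), and of its 279 lower genes 269, with one of 0.43 (40 higher, 0 lower called), with adjusted p = 0.345 and 0.112 with an estimated correlation. The count rests on single libraries: it was 377 without IL10R_P19_100, 17 without IL10R_P19_107, 21 without IL10R_P19_106, 47 without IL10R_P19_105, 284 without IL10R_68, and 52, 97 and 74 without IL10R_32, IL10R_61 and IL10R_67. Leaving out IL10R_27 gave 89 higher and 16 lower genes. Against CX, IL10R_P19 macrophages had 2 called genes (limma), Il10ra by -4.90 (SE 0.64) and Ppfia4 by 2.33 (SE 0.35), with 333 at an unadjusted p under 0.05 where chance gives 331. edgeR called 2 as well, with 426 at an unadjusted p under 0.05. Without CX 1 or CX 3 no gene was called by limma. An adjusted p that misses the threshold does not show that these groups were alike.

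The antibiotic groups asked whether the difference needs the intestinal bacteria. Between antibiotic-treated IL10R_abx (n = 4) and littermate_abx (n = 3) macrophages, 2 of 6612 genes were called. Il10ra was lower by 4.86 (SE 0.57, limma adjusted p = 2.162e-04), and Gbp2b, an interferon-inducible GTPase, was 272 ± 92.4 against 62.7 ± 7.33, higher by 2.04 (SE 0.24, adjusted p = 2.162e-04). Reg3g stood at 43.5, 3.76, 47.5 and 0 in the IL10R_abx libraries and at 1.03 to 3.16 in littermate_abx. In this pair Tnf differed by -0.16 (SE 0.44) and Il1b by -0.12 (SE 0.34), which did not pass. MHC class I genes had no called member over all genes and 8 of 16 higher adjusted over the list alone (median 0.54), with adjusted p = 6.28e-05 and adjusted p = 0.765 with an estimated correlation. Oxidative phosphorylation genes had 7 of 26 and interferon-gamma-inducible genes 3 of 14 higher adjusted over the list alone, each with adjusted p = 0.765 with an estimated correlation. Epithelial markers lay above 0 in 18 of 20 (median 0.32, 1 higher adjusted over the list alone), with adjusted p = 0.00989 and adjusted p = 0.765 with an estimated correlation. They took 0.31 to 0.50% of the reads in IL10R_abx and 0.27 to 0.41% in littermate_abx, which are overlapping ranges. Camera did not call the monocyte, neutrophil, dendritic, B and plasma cell or stromal markers (adjusted p = 0.758 to 0.891). An unadjusted p under 0.05 was found for 997 genes in limma, where chance gives 331, and edgeR called 2 (859 unadjusted). Without IL10R_abx_497 the count was 385, without IL10R_abx_495 it was 24, and without littermate_abx_491 it was 4.

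Antibiotic treatment itself went with the broadest differences of the series. IL10R_abx and IL10R macrophages differed in 3823 genes, 2020 higher and 1803 lower with antibiotics, and littermate_abx and CX in 2250, 1094 higher and 1156 lower. With antibiotics, Folr2 was higher by 4.51 (SE 0.60), F13a1 by 4.37 (SE 0.48), the monocyte attracting chemokines Ccl7 by 4.29 (SE 0.29) and Ccl2 by 4.11 (SE 0.28), and Cd163 by 4.19 (SE 0.37) in IL10R_abx, and Reg3b was lower by 6.52 (SE 1.38), Reg3g by 6.27 (SE 1.18), Clca4b by 5.68 (SE 0.99), the neutrophil antigen Cd177 by 5.07 (SE 0.32) and Plet1 by 5.02 (SE 0.77). Of 26 resident macrophage markers 24 were higher and 1 lower (24 and 1 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation), such as C1qa by 1.70 and Stab1 by 3.22. Of 24 lysosome genes 23 were higher (23 adjusted over the list alone), such as Cd68 by 2.25, and of 19 IL-10 and STAT3 response genes 15 (15 adjusted over the list alone), such as Etv3 by 2.25 and Sbno2 by 1.97. All 26 oxidative phosphorylation genes were lower (26 adjusted over the list alone), such as Cyc1 by -1.37, and all 20 epithelial markers were lower (20 adjusted over the list alone, median -2.13), such as Krt8 by -2.12, Krt19 by -1.90, Tff3 by -2.54 and Epcam by -2.03. For these 4 lists the adjusted p was 0.0946 with an estimated correlation. Of 24 stress genes 22 were higher and 1 lower (22 and 1 adjusted over the list alone, adjusted p = 0.171 with an estimated correlation), such as Klf2 by 2.64, of 26 NF-kB genes 22 higher and 2 lower (22 and 2 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation), and of 10 MHC class II genes 9 higher (10 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation), such as H2-Aa by 1.31. Chemokines were higher in 11 of 18 and lower in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). Of 6 pro-inflammatory cytokines 4 were higher and 1 lower (4 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0961). Tnf was higher by 1.75 (SE 0.39, adjusted p = 9.197e-04), and Il1b differed by 0.49 (SE 0.30), which did not pass. Il12b, tested here in the fit without a filter, was lower by -1.76 (SE 0.68, adjusted p = 0.0344). Among markers of other cells, stromal and endothelial ones were lower in 5 of 8, such as Col1a1 by -1.22. B and plasma cell markers were higher in 3 of 4 and lower in 1, and dendritic cell markers higher in 2 of 3. Monocyte markers were higher in 5 of 14 and lower in 6, and neutrophil markers higher in 1 of 5 and lower in 2. The counts adjusted over the list alone were the same for these 5 lists, and camera called none of them (adjusted p = 0.0775 to 0.421). The epithelial markers took 0.31 to 0.50% of the reads in IL10R_abx against 1.91 to 2.53% in IL10R, and 0.27 to 0.41% in littermate_abx against 1.49 and 1.66% in CX, so the share of epithelial RNA moved with each of these lists.

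In littermate_abx against CX, Cd163 was higher by 3.52 (SE 0.51) and Lyve1 by 3.48 (SE 0.48). Among the genes that fell were Retnlb by -4.67 (SE 0.63), Ang4 by -4.58 (SE 0.95), Clca1 by -3.92 (SE 0.78), Reg4 by -3.79 (SE 0.76) and Fcgbp by -3.39 (SE 0.51). Epithelial markers were lower in 17 of 20 (18 adjusted over the list alone, adjusted p = 0.0595 with an estimated correlation), oxidative phosphorylation genes in 24 of 26 (25 adjusted over the list alone), and IL-10 and STAT3 response genes were higher in 13 of 19 (13 adjusted over the list alone), such as Stat3 by 1.80, these with adjusted p = 0.0911 with an estimated correlation. Of the markers of other cells, stromal and endothelial ones were lower in 2 of 8, monocyte markers higher in 3 and lower in 4 of 14, neutrophil markers higher in 1 and lower in 2 of 5, and B and plasma cell markers higher in 1 of 4, the same adjusted over the list alone. Dendritic cell markers were higher in 1 of 3 and lower in 1 (2 and 1 adjusted over the list alone), and camera called none of these 5 lists (adjusted p = 0.172 to 0.804). The count was 1325 without CX 1 and 1443 without CX 3. No gene was called in either antibiotic comparison when the epithelial marker score of each library entered the model as a covariate, an alternative chosen after the data were seen, which raised the variance of the estimate 22.2 and 7.54 times. Tested directly, the deficiency effect differed between antibiotic-treated and untreated mice in 7 genes, all higher, chosen here because they are all that passed (limma, 699 at an unadjusted p under 0.05 where chance gives 331). They were Gbp2b (1.88), Amica1 (1.86), Hfe (1.42), Fcgrt (1.39), Rab11fip5 (1.31), Fcgr3 (1.28) and Batf3 (1.11), each with adjusted p = 0.0426. The count was 0 in limma without a trend and 0 with the epithelial score as a covariate. Without IL10R_abx_160 and IL10R_abx_161, left out together after the data were seen, it was 2, neither of them among the 7. It was 12 higher and 3 lower after quantile normalization, 18 with a stricter filter, 16 with these groups alone in the fit and 24 in edgeR. The untreated control of this test is CX and the treated one littermate_abx, whose genotype is not stated, so a difference between the control lines cannot be separated from the antibiotics. Amica1, for example, was 476 ± 78.7 in CX (SD, n = 2) and 119 ± 16.3 in littermate_abx (n = 3), but 147 ± 20.8 in IL10R (n = 5) and 134 ± 26.7 in IL10R_abx (n = 4). Resident macrophage markers differed as a list (median 0.99, 14 of 26 adjusted over the list alone), with adjusted p = 0.0947 with an estimated correlation. The count was 73 without IL10R_68, 15 without IL10R_abx_495, 1 without CX 1 and 0 without any other single library of these 4 groups.

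The last table asked whether neutrophils matter, by injecting an antibody against Ly6g, a neutrophil surface antigen, or a control IgG. The mice were bone marrow chimeras per the treatment label, which names the same injection for all 10 libraries, so the groups were taken from the titles. The titles of the wt libraries name no antibody, so comparisons with wt cannot separate the genotype from an injection. In ko_igg against wt, Reg3g was 6127 ± 4664 against 54.3 ± 71.2 (SD, n = 3 and 4, log2 change 7.31, SE 0.81, limma adjusted p = 6.007e-04). Reg3b was higher by 6.54 (SE 0.76), Lrg1 by 6.36 (SE 0.35), the tryptophan-degrading enzyme Ido1 by 5.60 (SE 0.82), Clca4b by 5.55 (SE 0.50) and Nos2 by 5.50 (SE 0.31). Lower were Mptx1 by -7.55 (SE 0.90), Hao2 by -6.41 (SE 0.58), the lectin Mgl2 by -5.20 (SE 0.81), Sycn by -4.75 (SE 0.41) and Tgm3 by -4.21 (SE 0.88). Tnf rose by 2.31 (SE 0.34), and Il1b differed by -0.35 (SE 0.71), which did not pass. Of 19 glycolysis and hypoxia genes 11 were higher (18 adjusted over the list alone, median 1.21), such as Slc2a1 by 1.37, Slc16a3 by 3.21 and Pkm by 1.21, and this list kept its call with an estimated correlation (adjusted p = 0.0035). Interferon-gamma-inducible genes were higher in 9 of 15 (11 adjusted over the list alone), such as Igtp by 2.32 and Socs1 by 2.79, MHC class I genes in 11 of 16 (13 adjusted over the list alone), such as Tap1 by 1.66, and antimicrobial genes in 9 of 20 (9 adjusted over the list alone), such as the siderophore-binding Lcn2 by 5.36 and Slpi by 2.74. These 3 lists had adjusted p = 0.344 with an estimated correlation. Resident macrophage markers were lower in 7 of 21 (12 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation), such as Cx3cr1 by -3.96 and Selenop by -2.00, and cell cycle genes higher in 5 of 23 (12 adjusted over the list alone, adjusted p = 0.55 with an estimated correlation), such as Ccna2 by 1.43. The cell cycle list had a median change of 0.79, while its score was 6.26 in wt 1 and 7.09 to 7.17 in the other wt libraries. Among markers of other cells, neutrophil markers were higher in 2 of 7, such as S100a9 by 4.96 (3 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation). Monocyte markers were higher in 5 of 16, such as Clec4e by 4.75 and Ly6c1 by 3.14 (5 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). Dendritic cell markers were lower in 2 of 3, Clec10a by -2.39 and Amica1 by -1.89 (3 adjusted over the list alone, adjusted p = 0.344 with an estimated correlation). Epithelial markers were higher in 2 of 19 (2 higher and 1 lower adjusted over the list alone), stromal and endothelial ones in 1 of 9 (1 adjusted over the list alone) and B and plasma cell ones in 0 of 4 (1 adjusted over the list alone), and camera called none of these 3 lists (adjusted p = 0.683 to 0.809). Of 6594 tested genes 606 were called, 378 higher and 228 lower. The count was 203 without ko_igg 14, 220 without ko_igg 16, 336 without wt 3, 342 without wt 4 and 1039 without wt 1, a library with Il10ra at 827, 1028567 reads and an epithelial share of 1.03% against 2.07 to 2.39% in the other wt libraries.

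Between ko_ly6g and ko_igg (n = 3 each) no gene was called by limma, with 127 at an unadjusted p under 0.05 where chance gives 330, and the smallest adjusted p was 1.00. No count test was run on this table, since whole reads were not recovered in 2 of its libraries. Reg3g was 4072 ± 2084 in ko_ly6g, and S100a9, a neutrophil calcium-binding protein, was 305, 463 and 26.2 in ko_igg and 16.7, 796 and 925 in ko_ly6g, against 1.84 to 8.93 in wt. Tnf differed by -0.45 (SE 0.36) and Il1b by -0.59 (SE 0.75), which did not pass. No list had a called member over all genes or adjusted over the list alone. Camera placed stromal markers lower (median -0.69, 8 of 9 below 0) and cell cycle genes lower (median -0.32, 21 of 23 below 0), with adjusted p = 0.229 and 0.495 with an estimated correlation. It placed monocyte markers lower (median -0.36, 3 of 16 above 0) and dendritic cell markers higher (median 0.70, 3 of 3 above 0), each with adjusted p = 0.438 with an estimated correlation. Neutrophil markers had a median of -0.12 and were not called (adjusted p = 0.629). In simulations of this comparison, with genes that varied independently, 54% of genes changed 2-fold and 88% of those changed 4-fold were recovered. Against wt, ko_ly6g macrophages had 286 called genes, 197 higher and 89 lower, led by Lrg1 at 6.89 (SE 0.35), Reg3g at 6.88 (SE 0.81), Reg3b at 6.20 (SE 0.76), S100a9 at 5.55 (SE 1.36) and the chemokine Cxcl5 at 5.44 (SE 0.77). Tnf was higher by 1.86 (SE 0.34, adjusted p = 0.016), and Il1b differed by -0.94 (SE 0.71), which did not pass. Glycolysis genes were higher in 8 of 19 (15 adjusted over the list alone, adjusted p = 0.00375 with an estimated correlation) and interferon-gamma-inducible genes in 7 of 15 (10 adjusted over the list alone, adjusted p = 0.32 with an estimated correlation). Neutrophil markers were higher in 3 of 7, such as S100a9 (3 adjusted over the list alone, adjusted p = 0.393 with an estimated correlation). Dendritic cell markers had no called member and 2 of 3 lower adjusted over the list alone (median -1.33, adjusted p = 0.425 with an estimated correlation). Monocyte markers were higher in 4 of 16 and lower in 1 (5 and 1 adjusted over the list alone), epithelial markers higher in 2 of 19 (2 adjusted over the list alone), and neither list was called by camera (adjusted p = 0.136 and 0.259). The count was 489 without wt 1, 103 without wt 3, 121 without wt 4, and 143 and 110 without ko_ly6g 5 and 7. Leaving out ko_ly6g 6 gave 67 higher and 38 lower genes. That an effect passed in 1 ko group and not the other was not tested apart from the direct comparison above.

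**Figure D2:**
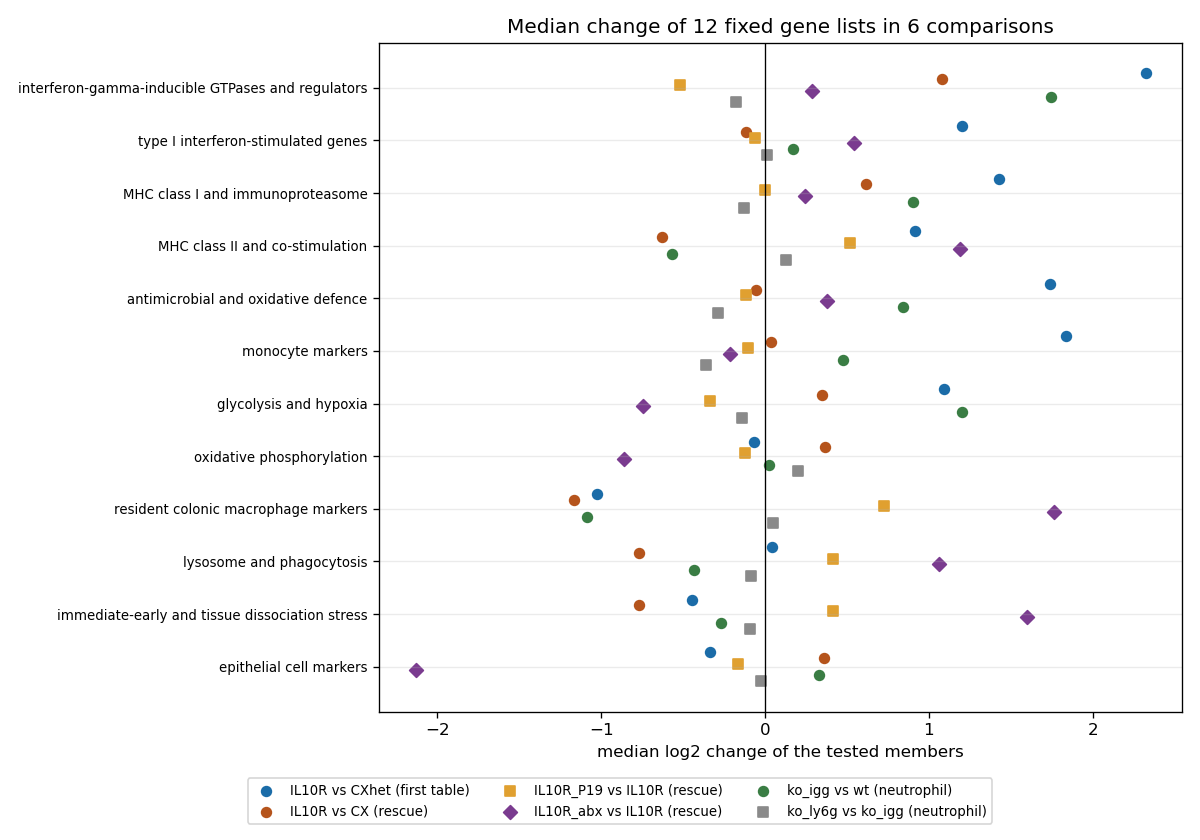
Median log2 change of the tested members of 12 fixed gene lists (vertical axis) in 6 comparisons (colours and marker shapes), on a linear axis with a line at 0. Interferon-gamma-inducible genes lie at 2.32 in IL10R against CXhet and resident macrophage markers at -1.02 there, at 0.73 in IL10R_P19 against IL10R and at 1.77 in IL10R_abx against IL10R.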

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

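All tests of single libraries in this part follow a rule for groups of 4 to 10 libraries fixed before any value was seen. The genes tested are those the text names, which were chosen by their values, and the interaction genes were named because they passed. The value given in brackets is the gap between the highest or lowest library and its nearest neighbour, divided by the range of the group. For normally distributed values chance gives such a gap in about 1 of 20 groups, so of 90 list scores 4.5 were to be found by chance and 14 were found, of 4 read totals 0.2 and 1, and of 561 gene groups 28.05 and 76. Gene values were tested untransformed, where a high library is more often set apart. Genes and lists also move together within a library, so the excess over chance is not a test.

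Among the list scores, IL10R_P19_100 was the lowest of its group for pro-inflammatory cytokines (0.898), resident macrophage markers (0.875) and lysosome genes (0.835) and the highest for cell cycle genes (0.919). IL10R_P19_105 was the highest for dendritic cell (0.913) and epithelial markers (0.870). IL10R_abx_495 was the lowest for MHC class II (0.836) and IL10R_61 for cell cycle genes (0.753). Library wt 1 was the highest for antimicrobial genes (0.837), MHC class II (0.844), B and plasma cell markers (0.891) and dendritic cell markers (0.911), and the lowest for oxidative phosphorylation (0.890) and cell cycle genes (0.907). IL10R_abx_497 had the highest read total of its group (0.855), at 1646887.

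Library IL10R_32 was highest in Acta2 (0.731), and lowest in H2-Ab1 (0.807) and Tnfsf9 (0.797). Library IL10R_68 was highest in Ang4 (0.925), Clca1 (0.870), Fcgbp (0.745), Igf1 (0.949), Mptx1 (0.879), Reg4 (0.882), Retnlb (0.879) and Stab1 (0.848). Library IL10R_abx_161 was highest in Ang4 (0.887), Ccl2 (0.888), Cd274 (0.858), Clec10a (0.931), Igtp (0.836), Nos2 (0.846), Pfkp (0.993) and Tnfsf9 (0.834), and lowest in Cd163 (0.857) and Ifi204 (0.833). Library IL10R_abx_160 was highest in C1qa (0.970), Il12b (0.862), S100a9 (0.890) and Slpi (0.831). Library IL10R_27 was highest in Ccl5 (0.808), Clec4e (0.937), Csf3r (0.746), Cxcl5 (0.857), Hp (0.907), Ido1 (0.748), Irg1 (0.770), Lcn2 (0.861), Lrg1 (0.863), S100a9 (0.971), Saa3 (0.897) and Slc16a3 (0.776). Library IL10R_P19_105 was highest in Ccr7 (0.900), Clca4b (0.867) and Reg3b (0.914). Library IL10R_P19_100 was highest in Cd177 (0.836) and Muc2 (0.864), and lowest in Cd68 (0.902), Cd93 (0.853), Col1a1 (0.854), Csf1r (0.895), Fcrls (0.844) and Rab11fip5 (0.852). Library IL10R_P19_107 was highest in Gbp4 (0.8294). Library IL10R_abx_495 was highest in Ido1 (0.889), and lowest in H2-DMa (0.859). Library IL10R_P19_106 was lowest in Slc16a3 (0.853). Library wt 1 was highest in Batf3 (0.925), C1qa (0.920), Ccl7 (0.859), Cd22 (0.930), Cd40 (0.899), Ciita (0.864), Dab2 (0.923), H2-Aa (0.893), H2-Ab1 (0.905), Hif1a (0.848), Il10ra (0.861), Il1rn (0.882), Lyve1 (0.849), Mrc1 (0.905), Ppfia4 (0.927), Psmb9 (0.862) and Socs1 (0.853), and lowest in Clca1 (0.833), Mptx1 (0.865) and Reg4 (0.956). Library wt 3 was highest in Ido1 (0.851). Library wt 2 was highest in Plet1 (0.903), Reg3b (0.927) and Reg3g (0.874).

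The difference of IL10R_abx from littermate_abx was unlike that of IL10R from CX, by a direct test that cannot separate antibiotics from the control line, in Amica1 (1.86), Batf3 (1.11), Fcgr3 (1.28), Fcgrt (1.39), Gbp2b (1.88), Hfe (1.42) and Rab11fip5 (1.31), as differences on the log2 scale (limma adjusted p = 0.0426 each). By camera it differed in the lists of chemokines (median 0.73), type I interferon genes (0.53), resident macrophage markers (0.99), MHC class II (0.62), lysosome genes (0.61), glycolysis (-0.28), cell cycle (-0.32), matrix remodelling (0.25), stress genes (0.53) and dendritic cell markers (1.32). Of these lists, only the dendritic cell markers were called with an estimated correlation (adjusted p = 0.00443).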

How the results depend on the processing

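Tests chosen only after the data were seen were edgeR on the recovered reads, the epithelial marker score as a covariate, and leaving out ko_igg 18 with ko_ly6g 5 or IL10R_abx_160 with IL10R_abx_161, and all others were planned. The count of called genes stayed within 1.5 times of the reported one except in the cases given here. With the covariate it was 1276 in IL10R against CXhet and 0 in IL10R against CX, IL10R_P19 against IL10R, IL10R_abx against IL10R, littermate_abx against CX and the interaction of deficiency and antibiotics. With a log2 change of at least 1 as well it was 277 in IL10R against CX, 64 in IL10R_P19 against IL10R, 1771 in IL10R_abx against IL10R, 1191 in littermate_abx against CX and 376 in ko_igg against wt. A further condition leaves fewer genes. With the compared groups alone in the fit it was 1093 in IL10R against CX, 6 in IL10R_P19 against CX, 16 in the interaction and 96 in ko_ly6g against wt. After quantile normalization it was 250 in IL10R_P19 against IL10R and 15 in the interaction. With edgeR it was 287 and 24 in these, and with a stricter filter 1 in IL10R_P19 against CX, 1 in IL10R_abx against littermate_abx and 18 in the interaction. The interaction had 0 without a trend in limma and 2, none of them among the 7 reported, without IL10R_abx_160 and IL10R_abx_161, and ko_ly6g against wt had 125 without ko_igg 18 and ko_ly6g 5. Elsewhere edgeR called 625 genes in IL10R against CXhet and 854 in IL10R against CX. It called 2 in IL10R_P19 against CX, 2 in IL10R_abx against littermate_abx, 3813 in IL10R_abx against IL10R and 2343 in littermate_abx against CX. Apart from fewer libraries or the further condition, the cause was not tested.

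Leaving out each library in turn gave 200 to 588 genes in IL10R against CXhet, 20 to 741 in IL10R against CX and 17 to 377 in IL10R_P19 against IL10R. It gave 0 to 2 in IL10R_P19 against CX, 2 to 385 in IL10R_abx against littermate_abx and 3616 to 3839 in IL10R_abx against IL10R. It gave 1325 to 2058 in littermate_abx against CX and 0 to 73 in the interaction. In the neutrophil table it gave 203 to 1039 in ko_igg against wt, 0 to 0 in ko_ly6g against ko_igg and 103 to 489 in ko_ly6g against wt. In the first table the correlations of same-numbered deviations were -0.06, 0.15 and 0.35. IL10R 3 correlated best with CXhet 3, and IL10R 2 about equally with CXhet 2 and CXhet 1 (0.15 each). IL10R 1 correlated best with CXhet 3 (0.12). With 3 libraries per group these values cannot tell whether the numbers pair the samples. With the number as a replicate block 808 genes were called, 561 of them shared with the reported 588. No paired analysis was possible in the other tables because the compared groups share fewer than 2 numbers.

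Camera called the lists below at the preset correlation and not at an estimated one. In IL10R against CXhet the adjusted p was 0.267 for cytokines, type I interferon, interferon-gamma, monocyte, neutrophil, antimicrobial, MHC class I and glycolysis, 0.46 for resident macrophage and NF-kB, 0.424 for MHC class II and 0.499 for stress. In IL10R against CX it was 0.265 for chemokines and glycolysis, 0.271 for interferon-gamma, MHC class I and epithelial, 0.254 for IL-10 response, MHC class II, oxidative phosphorylation, matrix and stress, 0.0545 for resident macrophage and lysosome and 0.433 for cell cycle. In IL10R_P19 against IL10R it was 0.47 for interferon-gamma, 0.0608 for resident macrophage and lysosome, 0.369 for antimicrobial, MHC class II, glycolysis, oxidative phosphorylation, epithelial and stromal, 0.5261 for cell cycle and 0.381 for matrix and stress. In IL10R_P19 against CX it was 0.314 for cytokines, chemokines, interferon-gamma and NF-kB, 0.261 for IL-10 response, resident macrophage, MHC class I, lysosome, oxidative phosphorylation, matrix and dendritic cell, 0.412 for MHC class II, 0.508 for cell cycle and 0.293 for stress. In IL10R_abx against littermate_abx it was 0.768 for type I interferon and resident macrophage and 0.765 for interferon-gamma, IL-10 response, MHC class I, oxidative phosphorylation, stress and epithelial. In IL10R_abx against IL10R it was 0.13 for chemokines and resident macrophage, 0.0946 for IL-10 response, lysosome, oxidative phosphorylation and epithelial, 0.213 for MHC class II, 0.159 for NF-kB and 0.171 for stress. In littermate_abx against CX it was 0.276 for chemokines, NF-kB, lysosome and stress, 0.0911 for IL-10 response and oxidative phosphorylation, 0.364 for resident macrophage and 0.0595 for epithelial. In the deficiency effect with against without antibiotics it was 0.233 for chemokines and MHC class II, 0.684 for type I interferon, 0.0947 for resident macrophage and lysosome, 0.502 for glycolysis, 0.681 for cell cycle and stress and 0.539 for matrix. In ko_igg against wt it was 0.344 for interferon-gamma, antimicrobial, MHC class I and dendritic cell, 0.369 for resident macrophage, 0.57 for monocyte, 0.531 for neutrophil, 0.739 for lysosome and 0.55 for cell cycle. In ko_ly6g against ko_igg it was 0.438 for monocyte and dendritic cell, 0.631 for antimicrobial and MHC class I, 0.229 for glycolysis, matrix and stromal and 0.495 for oxidative phosphorylation and cell cycle. In ko_ly6g against wt it was 0.5678 for type I interferon, 0.32 for interferon-gamma, resident macrophage, antimicrobial, MHC class I and matrix, 0.393 for neutrophil, 0.507 for lysosome, 0.681 for cell cycle and stress and 0.425 for dendritic cell. The first table's lower genes kept their call in ko_igg against wt (adjusted p = 0.00153, and 0.00458 with members changed by at least 1). Otherwise its higher and lower genes lost their calls, with adjusted p = 0.364 and 0.168 in IL10R against CX, 0.345 and 0.112 in IL10R_P19 against IL10R, 0.477 and 0.693 in IL10R_abx against littermate_abx and 0.364 and 0.0687 in ko_ly6g against ko_igg. The higher genes had 0.112 in ko_igg against wt and the lower ones 0.477 in IL10R_abx against IL10R. With members changed by at least 1, the lower genes had adjusted p = 0.0533 in IL10R_abx against littermate_abx at the preset correlation. With the same condition in both tables, IL10R against CX and ko_igg against wt shared 44 higher and 33 lower genes in place of 72 and 55.

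Of the results of named genes, 4209 kept direction and call over the settings other than leaving out 1 library, 390 lost the call, 13 gained it and 19 turned direction. Over the fits that left out 1 library the numbers were 2676, 614, 3 and 0. The 19 turned with the covariate, which raised the variance 22.2 times in IL10R_abx against IL10R and 7.54 times in littermate_abx against CX. In the former the log2 changes became 0.29 for Il10ra, 7.61 for Reg3b, 4.48 for Reg3g, 1.65 for Clca4b, 3.20 for Plet1, -0.75 for Ifi204, -1.16 for Trim30a, 0.27 for Ldha, 0.22 for Cyc1, -0.19 for Igf1, 0.48 for Col1a1 and 0.52 for Acta2. In the latter they became -0.31 for Ifi204, -0.092 for F13a1, -0.36 for Cd86, 0.32 for Aldoa, 0.13 for Ldha, 0.19 for Ndufb9 and 0.038 for Cyc1. Reg3b and Reg3g are themselves members of the covariate score, so their turned values are not independent of it.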

Other observations

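Tests chosen only after the result was seen were those of the other epithelial markers beside Reg3b and Reg3g, of the genes that were higher with antibiotics, and of the heat-shock and immediate-early genes beside Hspa8. The fits with the epithelial covariate and without IL10R_abx_160 and IL10R_abx_161 were also chosen after the data were seen.

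In IL10R_P19 against CX macrophages, where 2 genes passed, several gene lists were shifted as a whole at the preset correlation. Resident macrophage markers had a median change of -0.40, lysosome genes -0.29, dendritic cell markers -0.27 and stress genes -0.38, while MHC class I genes had 0.46 and interferon-gamma-inducible genes 0.63. With an estimated correlation the camera adjusted p was 0.261 for the resident, lysosome, dendritic cell and MHC class I lists, 0.293 for the stress list and 0.314 for the interferon-gamma list. In littermate_abx against CX, NF-kB genes had a median change of 1.07, stress genes 1.13 and chemokines 0.83 (adjusted p = 0.276 with an estimated correlation for each). In ko_ly6g against wt, resident macrophage markers had -1.03, MHC class I genes 0.78 and antimicrobial genes 0.72 (adjusted p = 0.32 with an estimated correlation for each).

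Reg3g, known with Reg3b as a product of gut epithelium, was called higher in deficient libraries of all 3 tables and Reg3b in 2 (4.88, SE 1.52, limma adjusted p = 0.0888 in the first). More epithelial RNA is a candidate explanation, although the sort kept CD45+ cells. The other epithelial markers, none of which another list holds, argue against a larger share of such RNA as the whole cause, as their median change was -0.40 (SD 0.52) in the first, 0.32 (SD 0.48) in the rescue and 0.12 (SD 1.05) in the neutrophil table, against at least 4.88, 7.86 and 6.54 for the Reg3 genes. Epithelial RNA was present all the same, with Krt19 at 5022 ± 589 and Muc2 at 3485 ± 1206 in IL10R of the rescue table (SD, n = 5), and Krt19 at 3875 ± 69.9 in CX (n = 2). Whether macrophages made the Reg3 transcripts, or epithelial cells that carried more of them at a steady share, was not tested and stays open. Since epithelial RNA was present, the cell source of other genes called in all 3 tables was not tested either. Examples are Clca4b and Plet1, which were higher, and Mptx1 and Cyp2c55, which were lower.

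The 3823 genes that differed between IL10R_abx and IL10R moved together with a lower share of epithelial RNA. With the epithelial score as a covariate 0 genes were called, but the score nearly follows the groups, as the variance rose 22.2 times, so the share and the treatment cannot be told apart for this count. Loss of epithelial RNA alone would raise all macrophage genes by 1 common factor. This is argued against for the 26 resident macrophage markers, since their changes had an SD of 1.15 against a root mean square SE of 0.301 (C1qa 1.70, Mrc1 3.20). The 2020 higher genes had 0.604 against 0.205. They were picked by this same comparison and need not be macrophage genes, so their spread decides nothing. IL10R_abx_160 and IL10R_abx_161 lay apart from IL10R_abx_495 and IL10R_abx_497 on the second principal component (17.4 and 24.1 against 4.52 and -4.87) and may be a cohort of their own, but they did not carry the count, as 3718 genes were called without them. A batch that parts all antibiotic from all untreated libraries could not be tested, and an effect of the antibiotics on the macrophages, which the design names, stays open too.

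Hspa8 was at 3712, 4786 and 4219.9 in CXhet and at 284, 311 and 209 in IL10R, and in the rescue table at 1333 and 1358 in CX and 1928 and 2654 in IL10R_abx_160 and IL10R_abx_161, against 320.4 and 457 in IL10R_abx_495 and IL10R_abx_497. A heat-shock response that differed between the groups is argued against, since the other 5 heat-shock genes had a median change of 0.14 (SD 0.26) against -3.99 for Hspa8. Dissociation stress stays open, since 16 of 19 immediate-early genes lay below 0 (median -0.75, SD 0.57), 4 of them called and the lowest Egr1 at -1.49, while the whole stress list had a camera adjusted p = 8.986e-04 and adjusted p = 0.499 with an estimated correlation. Hspa8 lies on the chromosome of Il10ra with 22 tested genes between them, so a sequence variant carried along with the targeted gene is a candidate explanation. Of the 99 tested neighbours of Il10ra 12 were called (12.1%), against 575 of 6665 other genes (8.63%, Fisher's exact test, 2-sided, p = 0.209), which leaves this open. An effect of the deficiency stays open. The deficient IL10R_abx_160 and IL10R_abx_161 lay above both CX libraries, but they had antibiotics and CX had none, so this cannot decide it. Hspa8 was not called lower in ko_igg. What parts IL10R_abx_160 and IL10R_abx_161 from IL10R_abx_495 and IL10R_abx_497, which share their label, was not tested.

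Other splits of the same libraries into groups of the same sizes were tested for 7 comparisons, at a share under 0.05 with no adjustment over the comparisons. At this unadjusted share chance is argued against for IL10R_abx against IL10R, with 3823 genes and at most 2824 in the other splits (1 of 100 drawn gave as many). The real split also gave the most genes for ko_igg against wt, with 606 and at most 247 (1 of 35). The same held for ko_ly6g against wt, with 286 and at most 196 (1 of 35). These comparisons share the wt libraries, and 1 of 35 is the lowest share possible, so over 7 comparisons chance is not excluded for them. Each share also takes the libraries as independent, which the labels do not state. For IL10R_P19 against IL10R, with 127 higher and 34 lower genes, 2 of 100 drawn splits gave as many, the real one included. That share is under 0.05, but the other split gave more genes than the real one, so chance is not called excluded here. This split, of IL10R_27, IL10R_32, IL10R_61 and IL10R_67 from the rest, gave 265, so that IL10R_68 grouped with the IL10R_P19 libraries. Chance cannot be excluded for IL10R_abx against littermate_abx, with 2 genes (7 of 35 splits). The split that set IL10R_abx_497 with the 3 littermate libraries gave 694, which points to a structure of these libraries. This is the real split with 1 library moved, and without IL10R_abx_497 the real groups differed in 244 higher and 141 lower genes. A masking of the genotype by this library was not told from a structure of another kind. The 10 splits of 3 against 3 libraries are too few for a share under 0.05, in IL10R against CXhet with 588 genes and at most 0 in the others (1 of 10), and in ko_ly6g against ko_igg with 0 and at most 1 (10 of 10).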
